A study of Mus musculus with 2 samples.

How the data were processed

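Mitral valve tissue was taken from wild-type mice and from mice heterozygous for the Fbn1 C1039G allele at 5 months of age, and 8 valves of each genotype were pooled into 1 RNA sample, per the labels. Total RNA was amplified with the Ovation RNAseq v2 system (NuGEN), turned into libraries with the Nextera XT kit and sequenced on an Illumina HiSeq system, per the labels' protocols. Per the submitters' processing notes the work used Trimmomatic, a read trimmer, HISAT2, a spliced aligner, kallisto, which estimates transcript abundance without full alignment, and the mm10 mouse genome. Versions, the role of each tool here, the gene annotation and how transcripts were added up to genes are not given in the sources used here. The deposited table holds 1 TPM value (an estimate of transcript abundance scaled for transcript length and library total) for each of 33640 gene symbols in each of the 2 libraries, per the file header, and the columns sum to 999964 and 999945.

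This processing bears on the values in several ways. The RNA was amplified, and the labels name no molecular identifiers, so reads are not independent molecules and low values can rest on few of them. TPM divides by transcript length, so that very short segments can reach a high TPM from few reads, and a smaller share of 1 abundant transcript raises all the others. Reads shared by near-identical genes (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Lyz1 and Lyz2) can be divided between them by an estimate. The depth of each library is unknown and TPM does not retain it, so no interval or detection floor was computed, and a value of 0 is described only as listed at 0.

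Both columns were matched to their libraries by the genotype in the label, and the 1 comparison was the mutant against the wild-type pool. With 1 library per genotype there is no replicate check, so no test was run and no p-value is given. The difference was log2(TPM + 1) in the mutant pool minus that in the wild-type pool, with a pseudocount of 1. This scale understates differences of low genes. A gene was counted as at least 2-fold higher or lower when this difference was at least 1 in size, among genes with a mean TPM of at least 1 over both libraries. Single genes were also ranked among the 500 genes nearest in mean TPM. The Pearson correlation of log2(TPM + 1) between the pools was 0.957 across these genes, which are not independent replicates.

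The comparison, 44 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were Fbn1, the Y-linked genes, the 15 largest positive and 15 largest negative differences among genes with a mean TPM of at least 10, and from each list the 2 most abundant members and the 2 with the largest difference among members with a mean TPM of at least 5. Some items that this rule takes are not reported here. Left out of the 30, by symbol, were Gm and Rik genes, symbols ending in -ps or in rs and a number, clone names, mitochondrial and ribosomal protein genes, Xist, Tsix and the 4 Y-linked genes. Other pseudogenes, such as the segments Traj8 and Traj14, and other X-linked genes, such as Timp1, were kept. Genes outside this rule in the main results were chosen after their values were seen, namely Ccl2, Ccl8, Isg15, Usp18, Mrc1, Folr2, Cd3d, Cd3e, Klrd1, Ptges, Tgfb1, Tgfb2, Tgfb3, Wnt9a, Notum, Reln, Alas2, Mpo, Camp, Retnlg, Nppb, Plac8, Treml4 and Gm20594. Further genes outside it are given under other observations, with how they were chosen. For each list the median difference of members with a mean TPM of at least 1 was given as a percentile among 10000 random lists of the same size, drawn from 20 bins of equal gene number by mean TPM with a fixed seed. A list was said to stand apart in the lowest or highest 2.5% of random lists, whatever the sign of its median. Lists with fewer than 4 measured members would have had no percentile, and there were none.

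The list method was tested on simulated data made from the 17004 genes of this comparison, with 100 lists for each setting. Without a shift, 3 of 100 lists of 8 genes, 5 of 15 genes and 3 of 30 genes stood apart. With all members shifted by 0.3, these numbers were 44, 59 and 92, and with a shift of 0.6 they were 93, 98 and 100. In such data a list of 8 genes with a common difference of 0.3 would therefore often be missed. Members of the fixed lists are co-expressed, so these rates need not hold for them.

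Alternatives were a pseudocount of 0.1 or 5, no filter or a mean TPM of at least 5, centring on the median over genes with a mean TPM of at least 10, quantile normalization, leaving out mitochondrial, globin, ribosomal protein, predicted and Rik genes, leaving out the muscle lists, and, for lists, the mean, members of 1 list alone and 50 bins. A further alternative, protein-coding genes with a transcript of at least 500 bases, was chosen after seeing the data. Gene coordinates, identifiers and transcript lengths were taken from GENCODE release M21, which uses the mm10 assembly, by symbol, and 32115 of the 33640 symbols matched, including 16489 of the 17004 with a mean TPM of at least 1. Calculations were done in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.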

Results

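RNA was sequenced from mitral valves of 5-month-old mice of 2 genotypes, wild type and heterozygous for the C1039G missense allele of Fbn1. Fbn1 encodes fibrillin-1, the main protein of extracellular microfibrils, and mutations of the human gene cause Marfan syndrome. The allele is carried by a mouse model of that disease. The comparison asks which genes are expressed at another level in the mitral valve of the mutant mice. Each genotype was represented by 1 library, made from a pool of 8 valves from male and female mice. There were therefore no replicates, no test and no error on any value, and every difference below is a difference between these 2 libraries. Values were TPM, a measure of transcript abundance scaled for transcript length and library total, for 33640 genes, which summed to 999964 in the wild-type and 999945 in the mutant pool. TPM keeps no record of sequencing depth, so the depth of both libraries is unknown. Where a pair of TPM values is given for a gene, the wild-type pool comes first and the mutant pool second. In all, 12542 genes were listed at 0 in the wild-type pool and 12222 in the mutant pool, of which 11034 were listed at 0 in both.

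Genes of neutrophils, monocytes, chemokines and interferon responses were higher in the mutant pool, with Lcn2, S100a9, Cxcl10 and Il1b among the largest differences. Transcripts of T cells, red blood cells, cardiac muscle, lymphatic endothelium and melanocytes were lower. Of the matrix genes, Postn and Timp1 had more TPM in the mutant pool, and Chad, Mfap4 and Mgp had less, while the collagen lists did not stand apart from other genes of similar abundance. Among 17004 genes with a mean TPM of at least 1, 818 were at least 2-fold higher and 293 at least 2-fold lower in the mutant pool on the log2(TPM + 1) scale, so that 73.6% of these genes were higher. Of the higher genes 133 were listed at 0 in the wild-type pool, and of the lower genes 92 were listed at 0 in the mutant pool. Of the 10145 genes with a mean TPM of at least 10, 209 were higher and 61 lower.

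The mutant pool had slightly more TPM for most genes. The median difference in log2(TPM + 1), mutant minus wild type, was 0.14 over genes with a mean TPM of at least 1 and 0.11 over those with at least 10. Differences of single genes are given as measured, and gene lists are set against random lists that share this shift. When differences were centred on the median, 659 genes were higher and 364 lower, a share of 64.4% higher. Quantile normalization gave 540 higher and 462 lower, a share of 53.9% higher. With mitochondrial, globin, ribosomal protein and predicted genes left out, the median over genes with at least 10 TPM was 0.06. The predicted gene Gm20594 alone took 10.4% of the TPM in the wild-type and 8.72% in the mutant pool. Ribosomal protein genes took 7.42% and 5.96%, and mitochondrially encoded genes 8.35% and 8.48%. Differences between the libraries were wider at low abundance, where the central 95% of genes with a mean TPM from 1 to 5 lay between −1.44 and 1.93, against −0.52 and 0.80 for genes from 50 to 200 TPM.

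**Figure D1:**
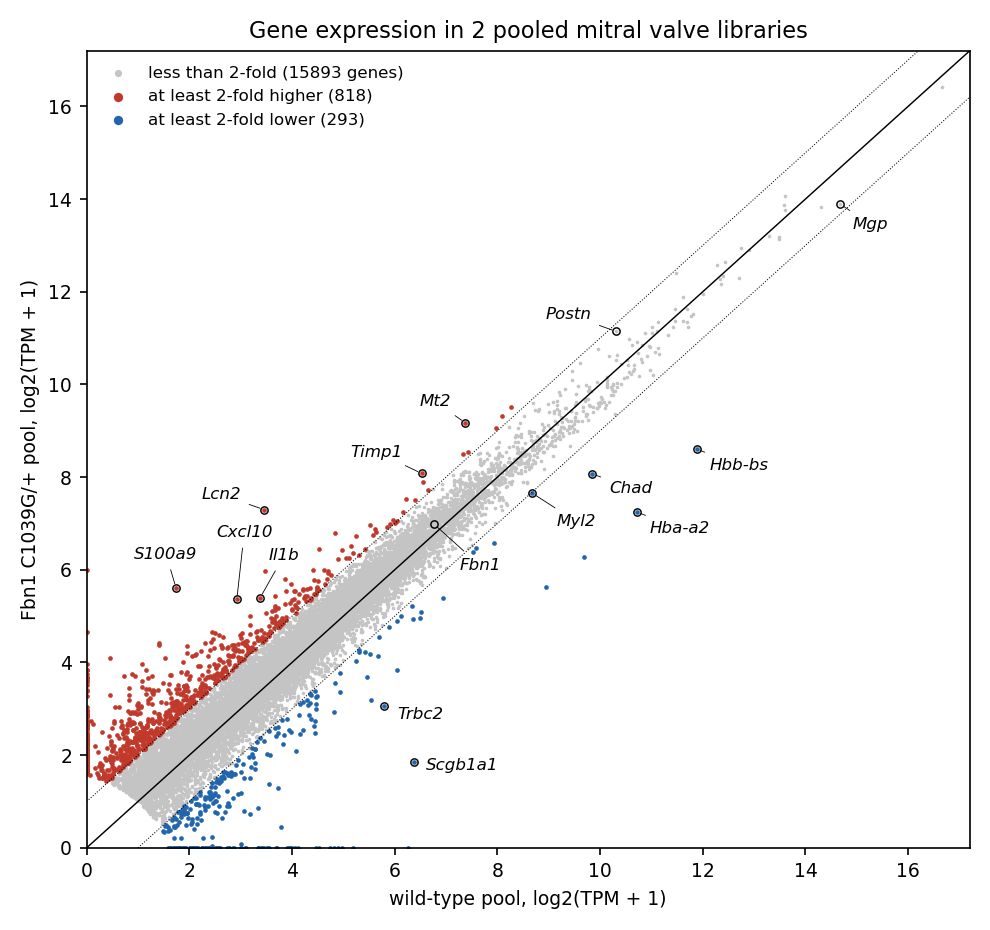
Gene expression in the 2 pooled libraries, with log2(TPM + 1) in the wild-type pool on the horizontal axis and in the Fbn1 C1039G/+ pool on the vertical axis. Each point is 1 of 17004 genes with a mean TPM of at least 1, red for 818 genes at least 2-fold higher and blue for 293 at least 2-fold lower in the mutant pool, the solid line marks equal values, dotted lines mark a 2-fold difference, and circled genes carry their names.

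Fbn1 itself was at 108 TPM in the wild-type pool and 126 TPM in the mutant pool. Its difference of 0.22 lay at percentile 64.6 of the 500 genes nearest to it in mean TPM. The gene lies on chromosome 2 at 125300594 to 125507993 (mm10, minus strand, ENSMUSG00000027204.13). The allele replaces an amino acid and need not alter the amount of mRNA, so this value does not check the genotype labels. The Y-linked genes, which report the share of male tissue in each pool, had more TPM in the mutant pool. Ddx3y was at 13.6 and 20.9 TPM, Eif2s3y at 24.7 and 32.0, Kdm5d at 18.1 and 26.1, and Uty at 44.8 and 64.5. Xist was not analysed here.

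The 15 genes furthest above, among those with a mean TPM of at least 10, are given here. Genes left out by symbol, such as Rik genes, are not ranked. S100a9, a calcium-binding protein abundant in neutrophils, was at 2.34 TPM in the wild-type and 48.0 TPM in the mutant pool, a difference of 3.87 (chromosome 3, 90692632 to 90695721). Lcn2, the iron-scavenging protein lipocalin-2, was at 9.95 and 156 TPM, a difference of 3.85 (chromosome 2, 32384633 to 32388252). Cxcl10, an interferon-induced chemokine, was at 6.595 and 40.2 TPM, and the cytokine gene Il1b at 9.42 and 41.2 TPM. The metallothionein Mt2 was at 165 and 576 TPM, the neutrophil-attracting chemokine Cxcl1 at 4.11 and 16.7 TPM, and Ptgs2, which encodes the inducible cyclooxygenase, at 14.9 and 50.5 TPM. Csf3r, the receptor for granulocyte colony-stimulating factor, was at 5.63 and 18.8 TPM. Timp1, an inhibitor of metalloproteinases, was at 90.9 and 269.9 TPM, the chemokine Ccl9 at 15.4 and 45.5 TPM, and the monocyte chemokine receptor Ccr2 at 11.8 and 35.0 TPM. Fmnl1, a formin of blood cells, was at 10.2 and 32.4 TPM. The histone demethylase Kdm4b (4.94 and 15.9 TPM), the carbonic anhydrase-related gene Car11 (6.89 and 23.0 TPM) and the receptor segment Traj11 (5.20 and 19.1 TPM) completed the 15.

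The 44 gene lists fixed before the data were examined were each summarised by the median difference of their measured members. Each median was placed among 10000 random lists of the same size and abundance. By this measure 8 lists stood apart on the higher side, in the highest 2.5% of random lists, and 12 on the lower side, in the lowest 2.5%. If genes varied independently, 2.2 of the 44 would lie outside these limits by chance. Members of a list are co-expressed, so a percentile describes these 2 libraries and is not a test of the genotype.

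**Figure D2:**
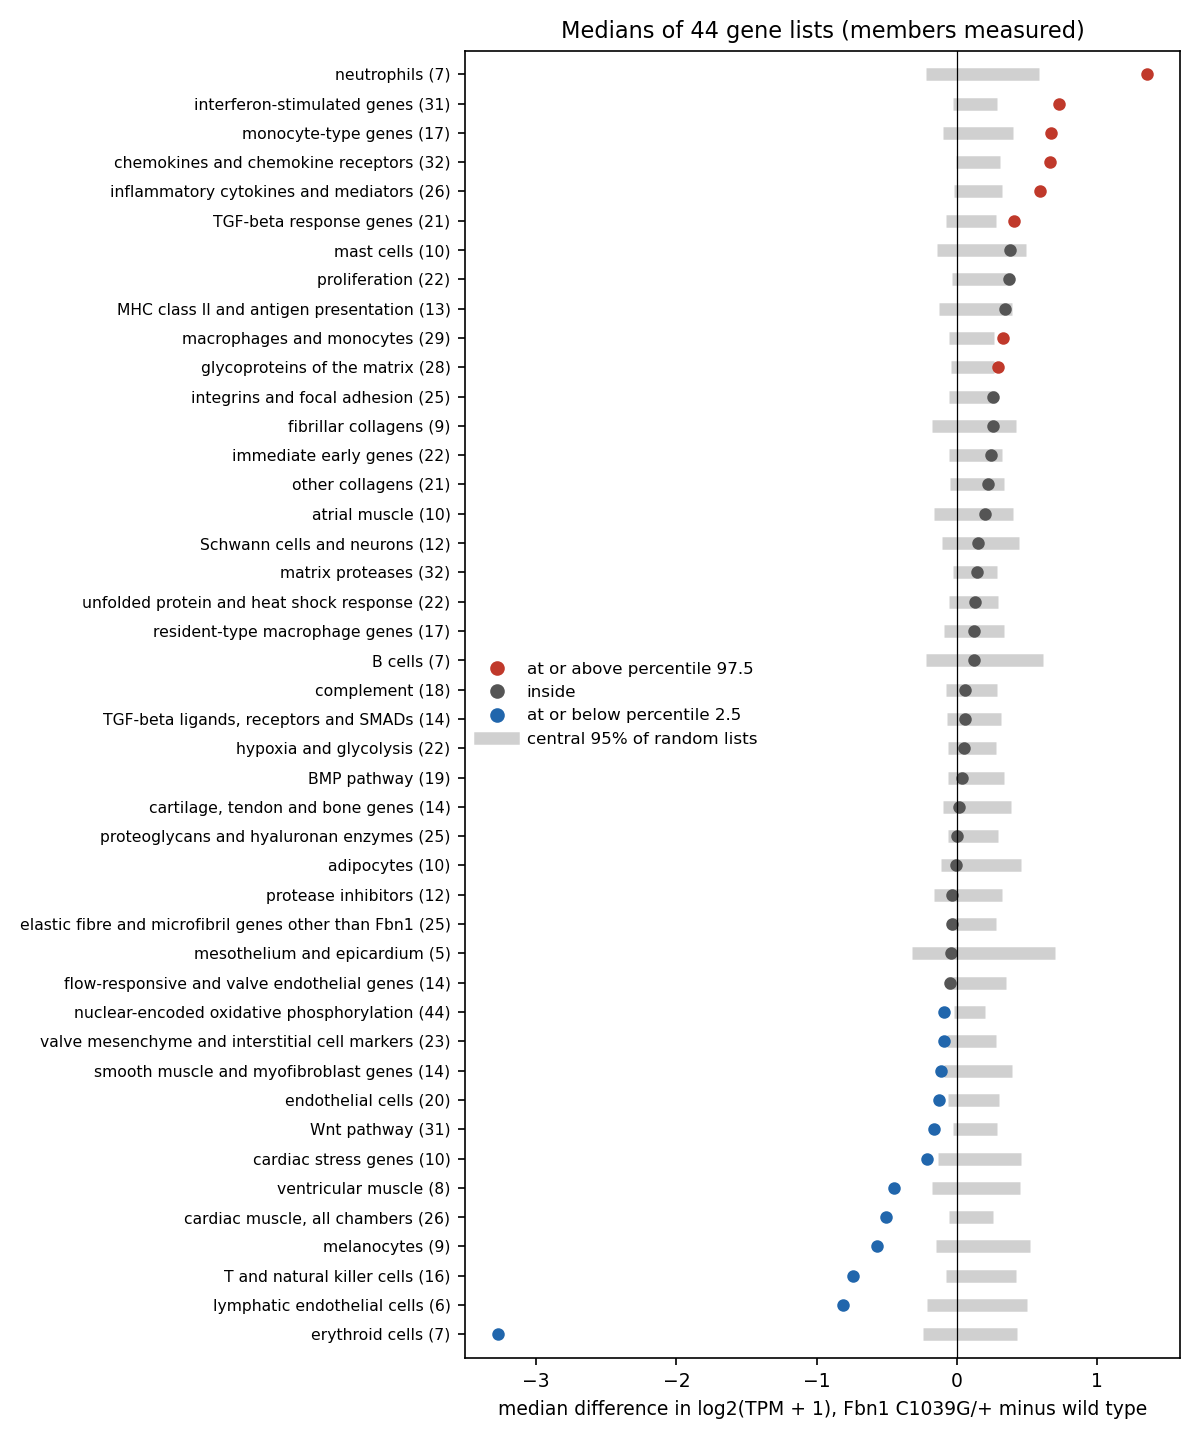
Median difference in log2(TPM + 1), Fbn1 C1039G/+ minus wild type, for each of 44 gene lists, with the number of measured members in brackets. Grey bars span the central 95% of 10000 random lists of the same size and mean TPM, and coloured points mark the 8 lists above (red) and the 12 lists below (blue) that range, from 1.36 for neutrophil genes to −3.28 for erythroid genes.

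Immune genes made up most of the lists on the higher side. The neutrophil list had 7 of its 14 members measured, with a median difference of 1.36 at percentile 100 (random lists −0.22 to 0.58). The others had a mean TPM below 1. Across the alternatives the median ran from 0.46 to 2.62, and the list stood apart under each. Of the measured members, S100a8, S100a9, Csf3r and Cxcr2 were at least 2-fold higher. S100a8, the partner of S100a9, was at 0.369 and 16.2 TPM and the chemokine receptor Cxcr2 at 6.43 and 18.02 TPM, while the granule genes Mpo, Camp and Retnlg were at 0.949 to 1.49 TPM in both pools. Interferon-stimulated genes had a median of 0.73 (percentile 100). All 31 measured members had more TPM in the mutant pool and 11 were at least 2-fold higher, among them Oas1a (4.57 and 14.6 TPM), an antiviral enzyme, and Ifi44 (5.76 and 16.8 TPM). The abundant members Ifi27l2a (339 and 429 TPM) and Ddx58 (140.3 and 206 TPM), the RNA sensor RIG-I, differed less. Chemokines and their receptors had a median of 0.66 (percentile 100), with 13 of 32 members at least 2-fold higher and none 2-fold lower. Ccl2 was at 30.6 and 85.1 TPM and Ccl8 at 36.9 and 105 TPM, whereas Ccl19 was at 116 and 104 TPM. Inflammatory cytokines and mediators had a median of 0.59 (percentile 100), with 7 of 26 at least 2-fold higher. The acute-phase gene Saa3 was at 447 and 707 TPM and the adhesion molecule Vcam1 at 259.7 and 362 TPM. The prostaglandin synthase gene Ptges was the 1 member at least 2-fold lower, at 18.5 and 8.16 TPM.

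Macrophage genes were covered by 3 lists, of which those of monocytes and of all macrophages stood apart. Genes of monocytes and monocyte-derived cells had a median of 0.67 (percentile 99.98), with 8 of 17 at least 2-fold higher. They included Ccr2, and their most abundant members were S100a4 (640.0 and 962 TPM) and Vcan (443 and 688 TPM). S100a4 is also in the valve mesenchyme list, and Vcan is also a proteoglycan of valve matrix. Some of the 8 had low TPM, such as Plac8 (listed at 0 and 5.29 TPM) and Treml4 (0.562 and 3.01 TPM), named after their values were seen. The broader macrophage and monocyte list had a median of 0.33 (percentile 99.7), with 2 of 29 members at least 2-fold higher. These were Ms4a6c (16.0 and 35.1 TPM) and Lyz1 (3.92 and 10.5 TPM), a near-identical copy of Lyz2 (1288 and 1587 TPM), from which its reads cannot be cleanly told apart. Genes of resident-type macrophages had a median of 0.12 (percentile 54.1) and no member at least 2-fold different. Selenop was at 1481 and 1475 TPM, Cd163 at 12.03 and 18.5 TPM, and Igf1 at 682 and 406 TPM. The medians of the monocyte-type and resident-type lists were not tested against each other. Genes of MHC class II and antigen presentation had a median of 0.34 (percentile 94.9), and reached percentile 99.99 when only members with a mean TPM of at least 5 were kept. Their co-stimulator Cd80 was at 2.41 and 8.06 TPM and H2-Aa at 739 and 887 TPM. Mast cell genes had a median of 0.38 (percentile 90.5), with the receptor Kit at 4.23 and 14.3 TPM, and stood at percentile 99.2 with members of at least 5 TPM alone. B cell genes (0.12, percentile 34.4) and complement genes (0.06, percentile 36.1) did not stand apart. The immunoglobulin gene Igkc was at 27.1 and 14.8 TPM, and the complement receptor gene C3ar1 at 27.3 and 42.5 TPM. Globin and T cell transcripts were lower in the same mutant library, as given below.

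Of the extracellular matrix lists, the glycoproteins alone stood apart, and single genes differed in both directions. Matrix glycoproteins had a median of 0.29 (percentile 98.8, random lists −0.04 to 0.27). Postn, a matrix protein of valve fibroblasts that responds to TGF-beta, was at 1269 and 2263 TPM and Sparc at 1506 and 2030.2 TPM. Tnc was the 1 member at least 2-fold higher, at 5.54 and 13.1 TPM, and Smoc1 was at 24.8 and 13.1 TPM. This result depended on the summary, since the mean of the members was 0.11 (percentile 41.0), and leaving out members shared with other lists gave a median of 0.05 (percentile 20.6). TGF-beta response genes had a median of 0.40 (percentile 99.9), and 19 of 21 had more TPM in the mutant pool. The cell cycle inhibitor Cdkn1a was at 514 and 681 TPM. Without members shared with other lists, such as Postn and Tnc, the median was 0.37 (percentile 94.995), inside the limits. TGF-beta ligands, receptors and SMADs had a median of 0.06 (percentile 29.7). Tgfb1 was at 25.8 and 33.1 TPM, Tgfb2 at 62.3 and 51.4 TPM, Tgfb3 at 79.4 and 58.8 TPM, and the inhibitory SMAD gene Smad7 at 17.7 and 27.0 TPM.

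Collagens did not stand apart. Fibrillar collagens had a median of 0.26 (percentile 83.6), with Col3a1 at 760.2 and 995 TPM, Col1a2 at 401 and 476 TPM and Col5a2 at 83.5 and 133 TPM. Other collagens had a median of 0.22 (percentile 82.3), with Col8a1 at 59.5 and 117 TPM and Col6a2 at 183 and 169.7 TPM. Elastic fibre and microfibril genes other than Fbn1 had a median of −0.04 (percentile 2.86, just inside the lower limit), which moved to percentile 2.33 when mitochondrial, globin, ribosomal protein and predicted genes were left out. Under quantile normalization the list lay at percentile 41.0, with a median of −0.03. The microfibril-associated genes Mfap4 (1248 and 661 TPM) and Mfap2 (65.6 and 35.2 TPM) had less TPM in the mutant pool, and the latent TGF-beta binding protein gene Ltbp4 was at 408 and 398 TPM. Proteoglycans and hyaluronan enzymes had a median of −0.0010 (percentile 12.3). Chad, which encodes the cartilage protein chondroadherin, was the 1 member at least 2-fold lower, at 919 and 268 TPM. The small leucine-rich proteoglycans Dcn (11409 and 9304 TPM), Bgn (5396 and 5161 TPM) and Ogn (175 and 101 TPM) also had less TPM. Cartilage, tendon and bone genes had a median of 0.02 (percentile 16.8), and −0.16 (percentile 1.91) with the same abundant genes left out. The list stayed inside the limits under 11 of 12 alternatives, and the percentile of these genes ran from 1.91 to 55.9. Mgp, an inhibitor of calcification and the most abundant of them, was at 26209 and 15196 TPM and Cytl1 at 1155 and 790.5 TPM, while Spp1, osteopontin, was at 26.1 and 44.4 TPM. Matrix proteases had a median of 0.14 (percentile 56.8) with Mmp2 at 338 and 374 TPM and Adamts8 at 12.9 and 24.3 TPM. Protease inhibitors had a median of −0.03 (percentile 19.95) but a mean of 0.21. Timp1 was at least 2-fold higher, while Cst3 (2246 and 1769 TPM) and Timp3 (2214 and 2270.2 TPM) were not. Integrins and focal adhesion genes had a median of 0.26 (percentile 95.3), with Flna at 246 and 339 TPM and Itga5 at 28.7 and 45.4 TPM, and reached percentile 97.6 among protein-coding genes alone. In the library these matrix values come from, the neutrophil, monocyte-type and broad macrophage lists were higher. The T and natural killer cell list and the lists of all-chamber and ventricular muscle were lower, while atrial muscle did not stand apart.

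Several lists of mesenchymal, endothelial and smooth muscle markers lay below other genes of their abundance. Valve mesenchyme and interstitial cell markers had a median of −0.10 (percentile 1.05), and their mean stood at percentile 3.61. The transcription factor gene Tbx20 was at 703 and 1253 TPM, Msx1 at 27.1 and 14.8 TPM and Vim at 2797 and 3167 TPM. Endothelial genes had a median of −0.13 (percentile 0.29), with 4 of 20 above 0. The VEGF receptor gene Kdr was at 18.5 and 12.3 TPM and Plvap at 15.6 and 10.8 TPM, while Pecam1 was at 223 and 241 TPM. Flow-responsive and valve endothelial genes had a median of −0.05 (percentile 3.65), which became −0.13 (percentile 0.65) over members with a mean TPM of at least 5. Across all alternatives the median of this list ran from −0.19 to 0.13 and its percentile from 0.41 to 47.9. Klf2, a transcription factor induced by shear stress, was at 61.9 and 44.1 TPM and the Notch ligand Jag1 at 19.5 and 13.7 TPM. Of the 14 members 7 were above 0, among them Thbd at 110 and 131 TPM. Lymphatic endothelial genes had a median of −0.81 (percentile 0), with Ccl21a at 244 and 94.3 TPM, Mmrn1 at 12.2 and 1.45 TPM and Reln at 4.60 and 1.20 TPM at least 2-fold lower, and the lymphatic regulator Prox1 at 26.7 and 22.6 TPM. This median ran from −0.97 to −0.27 across the alternatives, and the list stood apart under each. Smooth muscle and myofibroblast genes had a median of −0.11 (percentile 1.63). This became 0.11 (percentile 51.7) when members under 5 TPM were left out. Tagln was at 32.5 and 49.2 TPM, Rgs5 at 186 and 268 TPM and Mylk at 13.96 and 8.09 TPM. In the same library the neutrophil (1.36), monocyte-type (0.67) and macrophage (0.33) lists were higher, and the T and natural killer cell list (−0.74) was lower along with the lymphatic one.

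Wnt pathway genes had a median of −0.17 (percentile 0.02). Tcf7, a transcription factor of this pathway that T cells also express, was at 16.6 and 6.27 TPM, Wnt9a at 18.9 and 7.48 TPM and Notum at 1.99 and 0.361 TPM, and these were at least 2-fold lower. Sfrp4 was at least 2-fold higher, at 7.61 and 19.8 TPM, and the abundant Dkk3 was at 1617 and 1286 TPM. Without members shared with other lists the median was −0.02 (percentile 3.33), inside the limits, and with no filter on abundance it was 0 (percentile 6.14). BMP pathway genes had a median of 0.04 (percentile 19.8). Bmp4 was at 137 and 135 TPM and Id3 at 221 and 207 TPM.

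Of the 15 genes furthest below by the same ranking, 10 were T cell receptor segments or constant regions, 4 were globins and 1 was an airway gene. Traj18, Traj23, Traj24, Traj8, Traj12 and Trbj1-6 were at 21.1 to 35.5 TPM in the wild-type pool and listed at 0 in the mutant pool. These joining segments are 37 to 66 bases long, so few reads can give a high TPM. Of 55 receptor rows with a mean TPM of at least 1, 38 were at least 2-fold lower and 11 at least 2-fold higher. The constant regions Trbc2 (54.7 and 7.31 TPM) and Trbc1 (20.9 and 4.54 TPM) are longer and were also lower. Traj14 was at 45.2 and 8.14 TPM and Traj43 at 65.2 and 13.3 TPM. Scgb1a1, a secretory protein of airway club cells, was at 81.5 and 2.60 TPM, a difference of −4.52 (chromosome 19, 9083636 to 9087958). T and natural killer cell genes had a median of −0.74 (percentile 0), with 7 of 16 members at least 2-fold lower, among them Cd3e (19.2 and 6.35 TPM). Other settings gave this list medians from −1.02 to −0.12, and it stood apart under each. Klrd1, a receptor of natural killer cells, was the 1 member at least 2-fold higher, at 4.21 and 11.96 TPM. Cd3d was at 19.7 and 26.9 TPM and Thy1, which fibroblasts also express, at 143 and 152 TPM. Erythroid genes had a median of −3.28 (percentile 0), which rested on the globins. With globins and the other abundant classes left out, the median was −0.82 over 4 members (percentile 0.06). Hbb-bs was at 3769 and 388 TPM, Hbb-bt at 825 and 76.6 TPM, Hba-a2 at 1688 and 150.4 TPM and Hba-a1 at 492 and 48.4 TPM. The division of reads between the near-identical globin copies is uncertain, but all 4 differed alike, and their summed TPM was 6774 and 664. Of the other erythroid members, Alas2, the first enzyme of haem synthesis in red cells, was at 27.6 and 23.3 TPM.

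**Figure D3:**
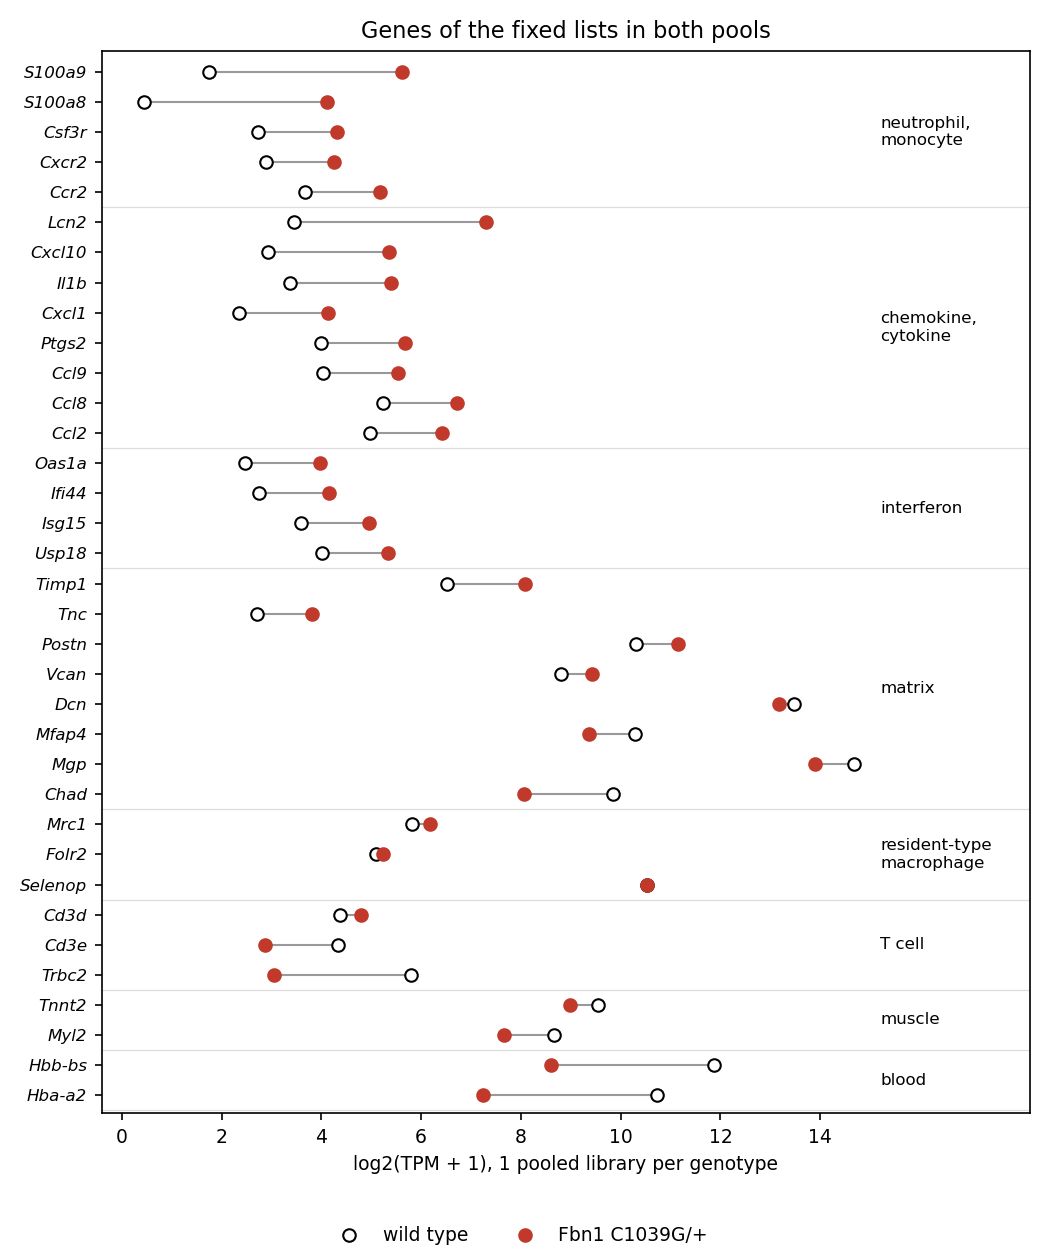
Expression of a selection of genes of the fixed lists as log2(TPM + 1) on the horizontal axis, with the wild-type pool as open and the Fbn1 C1039G/+ pool as filled circles, 1 pooled library per genotype. Ccl2, Ccl8, Isg15, Usp18, Mrc1, Folr2, Cd3d and Cd3e were chosen for the plot after their values were seen, and among the plotted genes the circles are furthest apart for S100a9 and Lcn2 on the higher side and Hba-a2 and Hbb-bs on the lower side (Hba-a1 and Hbb-bt are not plotted).

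Cardiac muscle transcripts were lower in the mutant pool. Of 26 genes of all chambers, 1 had a difference above 0, and the median was −0.51 (percentile 0). Troponin T (Tnnt2) was at 744 and 506 TPM, cardiac actin (Actc1) at 673 and 535 TPM and the fatty acid binding protein Fabp3 at 180.5 and 91.4 TPM. Ventricular genes had a median of −0.45 (percentile 0.05), with Myl2 at 407 and 201 TPM and Myl3 at 207 and 127 TPM, while atrial genes had a median of 0.20 (percentile 74.0), with Nppa at 117 and 179 TPM. Cardiac stress genes had a median of −0.22 (percentile 0.75), with Ankrd1 at 64.8 and 49.4 TPM and Acta1 at 19.7 and 9.38 TPM. Of the 10 members 2 were above 0, the natriuretic peptide genes Nppa and Nppb (7.87 and 10.9 TPM, named after its value was seen). Nuclear-encoded genes of oxidative phosphorylation, abundant in muscle, had a median of −0.09 (percentile 0.08), with Cox6c at 426 and 313 TPM and Atp5b at 1708 and 1639.8 TPM, the latter difference turning positive under quantile normalization. Summed over the muscle lists, TPM was 7051 in the wild-type and 5461 in the mutant pool.

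Melanocyte genes, which mark the pigment cells found in mouse valves, had a median of −0.57 (percentile 0). The pigment enzyme Dct was at least 2-fold lower, at 68.2 and 31.1 TPM, and the melanosome genes Pmel and Mlana were at 13.8 and 6.69 TPM and at 24.9 and 13.7 TPM. Adipocyte genes had a median of −0.0045 (percentile 12.1), with Scd1 at 66.1 and 41.8 TPM and Fabp4 at 23.6 and 14.7 TPM, and stood apart at −0.39 (percentile 0.13) over members with a mean TPM of at least 5. Schwann cell and neuron genes (0.15, percentile 46.6) and mesothelial genes (−0.05, percentile 17.1) did not stand apart, and the mesothelial median was −0.20 (percentile 1.14) with no filter on abundance. S100b was at 53.8 and 39.7 TPM, Tubb3 at 6.44 and 14.4 TPM, and Aldh1a2 at 16.4 and 10.9 TPM.

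Proliferation genes had a median of 0.37 (percentile 96.0), with the replication enzyme gene Top2a at 24.0 and 33.4 TPM and the mitotic kinase gene Aurkb at 7.38 and 12.8 TPM. The percentile was 98.5 with mitochondrial, globin, ribosomal protein and predicted genes left out, and 98.1 among protein-coding genes alone. Immediate early genes had a median of 0.24 (percentile 87.4), with Egr2 at 12.4 and 27.3 TPM, Egr1 at 132 and 158 TPM and Nr4a1 at 35.0 and 20.8 TPM. Genes of hypoxia and glycolysis had a median of 0.05 (percentile 26.9), with Hk2 at 20.9 and 36.2 TPM and Car9 at 10.8 and 5.03 TPM. Genes of the unfolded protein and heat shock response had a median of 0.13 (percentile 58.6), with the chaperone Hspa5 at 390.4 and 509.7 TPM and Asns at 3.56 and 8.85 TPM.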

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

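No paired analysis was possible because there was 1 library per genotype. The alternative of protein-coding genes with transcripts of at least 500 bases was chosen after seeing the data, and all others before. Of the 20 lists that stood apart, 15 did so under each of 12 alternatives where they could be computed, and of the 24 inside the limits, 15 stayed inside. Lists of muscle genes gave no value with muscle genes left out, nor did lists left with fewer than 4 members. Unknown depth limits the genes of low abundance most, and no alternative replaces the missing replicates. Of 172 genes that the rule names, 9 had a difference that changed sign under some alternative, all close to 0. These were Atp5b, Gapdh, Gata2, Hsp90b1, Ldha, Selenop, Ski, Thy1 and Timp3. Of the 51 named genes at least 2-fold different, 46 were so after centring, 45 after quantile normalization and 40 with a pseudocount of 5.

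The count of genes at least 2-fold higher (818) was 1264 with a pseudocount of 0.1, 209 with a pseudocount of 5, 360 at a mean TPM of at least 5, 540 after quantile normalization, 499 without mitochondrial, globin, ribosomal protein, Gm and Rik genes and 367 among protein-coding genes. The count of lower genes (293) was 464 with a pseudocount of 0.1, 87 with 5, 103 at a mean TPM of at least 5, 462 after quantile normalization and 126 among protein-coding genes. Pseudocount and filter act by construction on genes of low TPM, and for the scalings the cause was not tested. All 540 genes higher after quantile normalization were among the 818, and all 293 lower genes were among the 462. The Fbn1 difference (0.22) was 0.105 after centring and 0.0912 after quantile normalization, and the median of the Y-linked genes (0.51) was 0.40 and 0.38.

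With members shared between lists left out, the medians were 0.0488 for matrix glycoproteins (percentile 20.6, below the median of random lists), 0.37 for TGF-beta response genes and −0.0226 for the Wnt pathway, each then inside the limits with fewer genes. With the mean in place of the median, matrix glycoproteins were at 0.11 (percentile 41.0, again below the middle of random lists), and they, valve mesenchyme at −0.0666 and smooth muscle at −0.12 were all inside. In the other direction the means of MHC class II genes (0.46) and adipocyte genes (−0.21) stood apart. At a mean TPM of at least 5, smooth muscle genes turned to 0.11, and MHC class II (0.64), mast cell (0.63), adipocyte (−0.39) and flow-responsive genes (−0.13) stood apart. With no filter the Wnt median was 0 and inside, and flow-responsive (−0.15) and mesothelial genes (−0.20) stood apart. A pseudocount of 5 gave 0.20 for glycoproteins, inside, and 0.31 for MHC class II, apart. Quantile normalization gave 0.13 for glycoproteins, inside, and 0.38 for MHC class II, apart. Without mitochondrial, globin, ribosomal protein, Gm and Rik genes, elastic fibre (−0.0912), cartilage (−0.16) and proliferation genes (0.34) stood apart, and the erythroid median, without its globins, was −0.82 over 4 members and still apart. Proliferation (0.37) and integrin genes (0.26) stood apart among protein-coding genes. The cause of these list differences was not tested. Centring, quantile normalization and leaving out abundant genes turned the sign of no list standing apart, whereas medians near 0 of lists inside, such as TGF-beta ligands and BMP genes, did turn.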

Other observations

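Beyond the receptor, globin and airway genes, some further genes with a mean TPM of at least 10 were at least 2-fold lower in the mutant pool, and the examples were chosen after their values were seen. Bglap2, an osteocalcin gene, was at 123 and 40.8 TPM and Ucma, a cartilage matrix protein gene, at 50.3 and 16.5 TPM, although none of the 14 measured genes of the fixed cartilage, tendon and bone list was 2-fold lower and that list did not stand apart (percentile 16.8). The prostaglandin D synthase gene Ptgds was at 89.1 and 30.3 TPM, the peptidase gene Mme at 29.5 and 9.36 TPM, the urotensin receptor gene Uts2r at 89.7 and 33.2 TPM and the transcription factor gene Aff3 at 80.9 and 29.9 TPM. Cbs, an enzyme of homocysteine metabolism, was at 20.6 and 5.16 TPM. Mt1, which lies beside Mt2 and also encodes a metallothionein, was at 141 and 238 TPM.

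Some genes of the circadian clock differed in opposite directions, in lists made after some of their values were seen, so that the contrast between the lists is not tested. Among 11 genes of the arm that includes the Per genes and Dbp, 9 had more TPM in the mutant pool, with Per1 at 22.6 and 37.8 TPM and Nr1d1 at 287 and 369 TPM. Among 6 genes of the opposite phase, 5 had less, with Arntl at 19.6 and 8.87 TPM and Npas2 at 10.4 and 3.07 TPM, and Cry1 (2.79 and 4.04 TPM) had more.

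Of the tests that follow, those of short receptor segments, whole blood and cardiac muscle were chosen after the result was seen, and those on further thymus, airway, neutrophil and clock genes were set before those genes were looked at. The cardiac muscle test replaced earlier ones that decided nothing, a rescaling of each gene by 1 factor and the percentile of the endothelial list alone, and the receptor segment test replaced a limit on length that removed no gene of the list. Also after the results were seen, it was settled that an explanation is set aside only when its genes lay in the opposite 2.5% of random lists.

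T cell genes and the airway gene Scgb1a1 were higher in the wild-type pool. Inflated TPM of short receptor segments is argued against as the whole cause by T cell genes of ordinary length. The 14 T and natural killer cell genes of the list that are not receptor rows each have a longest transcript of 881 bases or more. Their median was −0.40 at percentile 0.01, although 5 of them were above 0. The list held no joining segments. Only 2 rows, the constant regions Trbc1 and Trbc2, were left out, and the whole list already stood at percentile 0. The percentile without these 2 rows was therefore largely fixed in advance. One hypothesis is that thymus tissue may have been carried into the wild-type pool, since Rag1 (4.39 and 0.183 TPM) and Dntt (7.60 TPM and listed at 0) mark immature T cells, but 21 further thymocyte genes had a median of 0.04 at percentile 12.4, Ptcra (3.74 and 3.49 TPM) and Rag2 (3.69 and 3.82 TPM) differed little, and some of the 21, such as Coro1a and Ikzf1, are also genes of other leukocytes. Airway tissue was prompted by Scgb1a1, Scgb3a2 (5.85 TPM) and Bpifa1 (12.05 TPM), the last 2 listed at 0 in the mutant pool. The 10 of 22 further lung and airway genes with a mean TPM of at least 1 had a median of −0.06 at percentile 7.26. Both carry-over explanations stay open because their further genes lay inside the limits on the lower side. For the T cell genes, carry-over cannot be told apart here from a difference in T cells between the genotypes, which 1 pool each cannot test. A difference in T cells does not bear on airway genes such as Scgb1a1, whose source stays open.

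Neutrophil and monocyte genes were higher in the mutant pool while globins were lower. More whole blood in the mutant pool is argued against by the globins, of which the one that differed least was still at −3.28. Less cardiac muscle would raise the genes of all other cell types alike. Yet 24 neutrophil and monocyte-type genes had a median of 0.86 and 20 endothelial genes one of −0.13, and medians of opposite sign argue against it as the whole cause. The difference of 0.99 lay at percentile 100 of matched random pairs of lists (central 95% from −0.25 to 0.30). These lists already stood apart on opposite sides, so that percentile was fixed in advance and adds nothing. The muscle lists summed to 7051 and 5461 TPM, of column totals of 999964 and 999945. Less of these listed genes could therefore raise others only slightly, which falls far short of a median of 0.86. Muscle transcripts outside the lists are not in these sums. Leaving the muscle lists out moved the counts little, to 817 genes higher and 294 lower, against 818 and 293. More neutrophils, or activated myeloid cells that share their genes, may account for part of it, since the 17 of 25 further neutrophil genes with a mean TPM of at least 1 had a median of 0.57 at percentile 99.9 with 14 above 0, but the 4 at least 2-fold higher had low TPM (Clec4e at 1.18 and 4.20 TPM, Slfn4 at 0.452 and 5.66 TPM, and Fpr2 and Stfa2l1 at 3.90 and 6.18 TPM in the mutant pool and listed at 0 in the wild-type pool), Sorl1 (22.02 and 12.999 TPM) was lower, and Lrg1 (23.6 and 23.2 TPM), Pglyrp1 (19.7 and 19.0 TPM) and the low granule genes Mpo, Camp and Retnlg of the fixed list lay below the middle of the genes nearest to them in mean TPM. Whether this follows from the genotype or from single animals within the pool of 8 stays open and was not tested.

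For the opposed clock genes, collection of the pools at different times of day may be the cause. However, 8 further clock outputs not looked at before had a median of 0.01 at percentile 20.7, 4 of them above 0, with Usp2 (16.9 and 29.9 TPM) and Coq10b (16.7 and 31.8 TPM) going with it and Por (93.1 and 70.3 TPM) against. The bound set beforehand against this explanation, a percentile below 50, was met, but the value lay well within the random lists (−0.15 to 0.45), so collection time, genotype and chance cannot be told apart by these genes.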
